A study of Capra hircus with 12 samples.

How the data were processed

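RNA from the lactating mammary gland of 12 goats was measured on 12 2-colour arrays of bovine long oligonucleotides. Each array compared 1 goat deprived of food for 48 h with 1 goat fed a control diet without restriction. There were 6 such pairs of goats, called comparisons here, and each was hybridised on 2 arrays with the dyes exchanged. The goat RNA was read by probes designed on another species, so the strength of a probe also depends on how well the sequences match.

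Per the file headers, the authors read the spots with ImaGene 6.0.1, and the deposited scanner values are the signal and background intensity of each dye channel, without normalization. An array holds 19200 spots in 48 print blocks, with 8379 probes in 2 spots each and 2442 control spots. The authors also deposited a log2 ratio per spot. Its direction and normalization are not given in the sources used here. Set against a loess ratio of the signal without background correction, it had an r of 0.984 to 0.998 across spots and a slope of 0.965 to 0.997 on the 12 arrays, as food-deprived over control in both dye orientations. Spots of an array are not independent replicates. The median of the deposited log2 values was 0.0094 and -0.0042 on the arrays of comparison 1, 0.016 and -0.0085 on those of comparison 2, and 0.020 and -0.013 on those of comparison 3. It was 0.025 and -0.0088 for comparison 4, 0.029 and -0.016 for comparison 5, and 0.016 and -0.010 for comparison 6.

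Ratios were computed from the scanner values with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, and each array was normalized by loess with a span of 0.3 and a weight of 0 for control spots. Spots marked by hand or as poor, 12 to 40 and 0 to 4 per channel, were left out. The 4206 to 7382 spots per channel marked as empty were kept and left to the detection rule. Both spots of a probe were averaged, then both arrays of a comparison, which gave 6 log2 ratios of food-deprived over control per probe. A spot was detected when its signal exceeded the background mean by 2 background SDs. Probes detected in at least 6 of the 12 channels of a diet were tested, which left 6676.

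The 6 ratios were tested against 0 with limma's moderated test and adjusted by the Benjamini-Hochberg method at 0.05. The number with at least a 1.5-fold change was counted as well. Errors are given as the SD over the 6 comparisons. On simulated data for this comparison, run on 6676 probes, the test recovered 98% of 50 changes of 1.2-fold and 96% of 50 of 1.3-fold. It recovered 98% of 50 of 1.5-fold and 100% of 50 of 2-fold, and 11 of its 207 calls were false. The simulation drew noise independently for each probe and began after background correction and loess. It therefore tested neither correlation between probes nor these 2 steps. The dye effect was tested in the same way on the mean of both arrays without turning the sign.

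Gene symbols came from the table that pairs the probes with genes. One symbol was given for 6840 probes, several for 93 and none for 1446. Of the 6535 distinct symbols, 6020 also occur in the goat RefSeq table. A gene with several probes was represented by the brightest, except where all its probes are described. A total of 29 gene lists on lactation, metabolism, protein synthesis, cell death and signalling and 10 sets of cell type markers were tested with camera at a preset correlation of 0.01, adjusted over all sets with at least 3 measured genes. Of the 39 sets, 38 had as many, over 5278 genes with values in all 6 comparisons. Camera with an estimated correlation, fry and a two-sided exact sign-flip permutation test of the mean of a set were run beside it. The smallest p the 64 sign patterns of 6 comparisons allow is 0.03125. On simulated data, run on 6653 probes, camera called 4 of 4 sets of 12 genes shifted by 0.15 and 0 of 40 unshifted sets. The simulated genes of a set were not correlated, so false calls from correlated genes were not tested. Nor were shifts as small as the mean of 0.063 found for cytosolic ribosomal proteins.

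The lists, the tests, the thresholds and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls among genes past the adjusted threshold and of one sign in all 6 comparisons, every measured milk protein, and up to 4 members with the smallest p for any other list that is described. A probe without a gene name is named only among the 2 largest rises or falls. Genes named outside this rule are said to have been chosen after their values were seen.

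Alternatives fixed at the same time covered background correction, signal and background estimates, normalization within and between arrays, the detection filter, marked spots, the use of both spots and both arrays, the pairing, the variance model, weights, leaving out each comparison, the deposited ratios, and for the lists the test and the choice of probe. Scan session as a block, each scan session alone and removal of a trend on the dye effect were chosen after seeing the data. By the date in the file headers, comparisons 1 to 3 came before comparisons 4 to 6, each group with both diets. These 2 groups are called scan sessions here. Whether that date is the day of scanning or of spot reading, and whether each group was a single session, was not established. Probes with several symbols were counted but not used in lists, and none is named except that of CSN3 and CSN2. Animals' records beyond the diet were not used here.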

Results

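Mammary gland RNA was compared between 6 lactating goats deprived of food for 48 h and 6 lactating goats on a control diet fed without restriction. Each food-deprived goat was hybridised together with 1 control goat on 2 arrays with the dyes exchanged, so that n = 6 pairs of goats, called comparisons. Median probe signal lay between 114 and 263 intensity units per channel, over a median background of 33.8 to 91.5. Between 61.4 and 87.2% of the probe spots of a channel were detected, against 0.0819 to 1.31% of the blank control spots. At most 4 spots of a channel were saturated. The number of goat pairs limits the precision. Values are log2 ratios of food-deprived over control, so each compares the diets within 1 probe.

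The comparison asked how 48 h without food affects the transcripts of a gland in full milk synthesis. Among genes past the adjusted threshold, those of the milk proteins LALBA, CSN1S2 and CSN1S1 fell furthest. LALBA, the subunit that turns a galactosyltransferase into lactose synthase, was 1.93-fold lower in food-deprived goats (log2 ratio -0.95 ± 0.45, SD, n = 6; limma adjusted p = 0.00121). CSN1S2, a calcium-binding casein, was 1.81-fold lower (-0.86 ± 0.48; adjusted p = 0.00317). CSN1S1, another casein, was 1.54-fold lower (-0.62 ± 0.25; adjusted p = 6.60e-04). MT1A, a metal-binding metallothionein, rose most, by 1.62-fold (0.70 ± 0.58; adjusted p = 0.0288), with values from 0.042 to 1.54 across the comparisons.

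All 3 milk protein genes were lower in 6 of 6 comparisons and stayed past the threshold without any single comparison. Their calls did depend on the variance model, as none of the 3 was called with unmoderated variances. Of 33 other settings, 2 lost the call of LALBA, 3 that of CSN1S2 and 3 that of CSN1S1. LPO, the antibacterial peroxidase of milk, passed as well, with a small change (-0.12 ± 0.072; adjusted p = 0.0437). Its call was lost without any one of comparisons 2, 3, 4, 5 and 6, with adjusted p up to 0.129, and the second array of each comparison alone gave 0.032. Of the 10 milk protein genes measured, 4 fell over all probes tested and 7 fell when adjusted over the list alone, the further 3 being GLYCAM1, CSN3 and PAEP. GLYCAM1, a secreted mucin-like protein, had -0.14 ± 0.12 (adjusted p = 0.0690), and CSN3, the casein that stabilises micelles, had -0.23 ± 0.27 (adjusted p = 0.124). On the second array alone these were 0.039 and 0.093. A dimmer probe of CSN3 gave -0.19. A brighter probe, paired with both CSN3 and CSN2 and chosen after its value was seen, was called lower. It had -0.48 ± 0.11 over the 4 comparisons with values, without comparisons 4 and 6 (limma adjusted p = 4.77e-04). No tested probe carries the casein CSN2 alone. PAEP, the whey protein beta-lactoglobulin, had -0.31 ± 0.38 (adjusted p = 0.139), SPP1, the phosphoprotein osteopontin, -0.58 ± 0.91 (adjusted p = 0.238), and MFGE8, a coat protein of the milk fat globule, -0.21 ± 0.36 (adjusted p = 0.308). LTF, the iron-binding lactoferrin, had 0.26 ± 0.62 (adjusted p = 0.451).

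As a list, milk proteins were lower by camera (mean -0.37 ± 0.071 over the 6 comparisons, median -0.27; adjusted p = 1.79e-05). Their mean was below 0 in all 6 comparisons (exact sign-flip p = 0.03125). With an estimated correlation the adjusted p was 0.0671. The mean was -0.38 in the first scan session, comparisons 1 to 3, and -0.37 in the second, comparisons 4 to 6, and with session as a block the adjusted p was 2.38e-06. The session means of single genes were further apart, with LALBA at -1.32 and -0.58, CSN1S2 at -1.20 and -0.52, CSN1S1 at -0.78 and -0.47, SPP1 at -0.017 and -1.14, and LTF at 0.69 and -0.16. No probe differed between sessions in limma at an adjusted p of 0.05, and 303 did at an unadjusted p of 0.05, where chance gives 333.8. Once intensities had been made alike in distribution between arrays, the signal of the only CSN1S1 probe was lower in the second session. It was 7.40-fold lower in food-deprived goats and 9.16-fold lower in control goats.

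**Figure D1:**
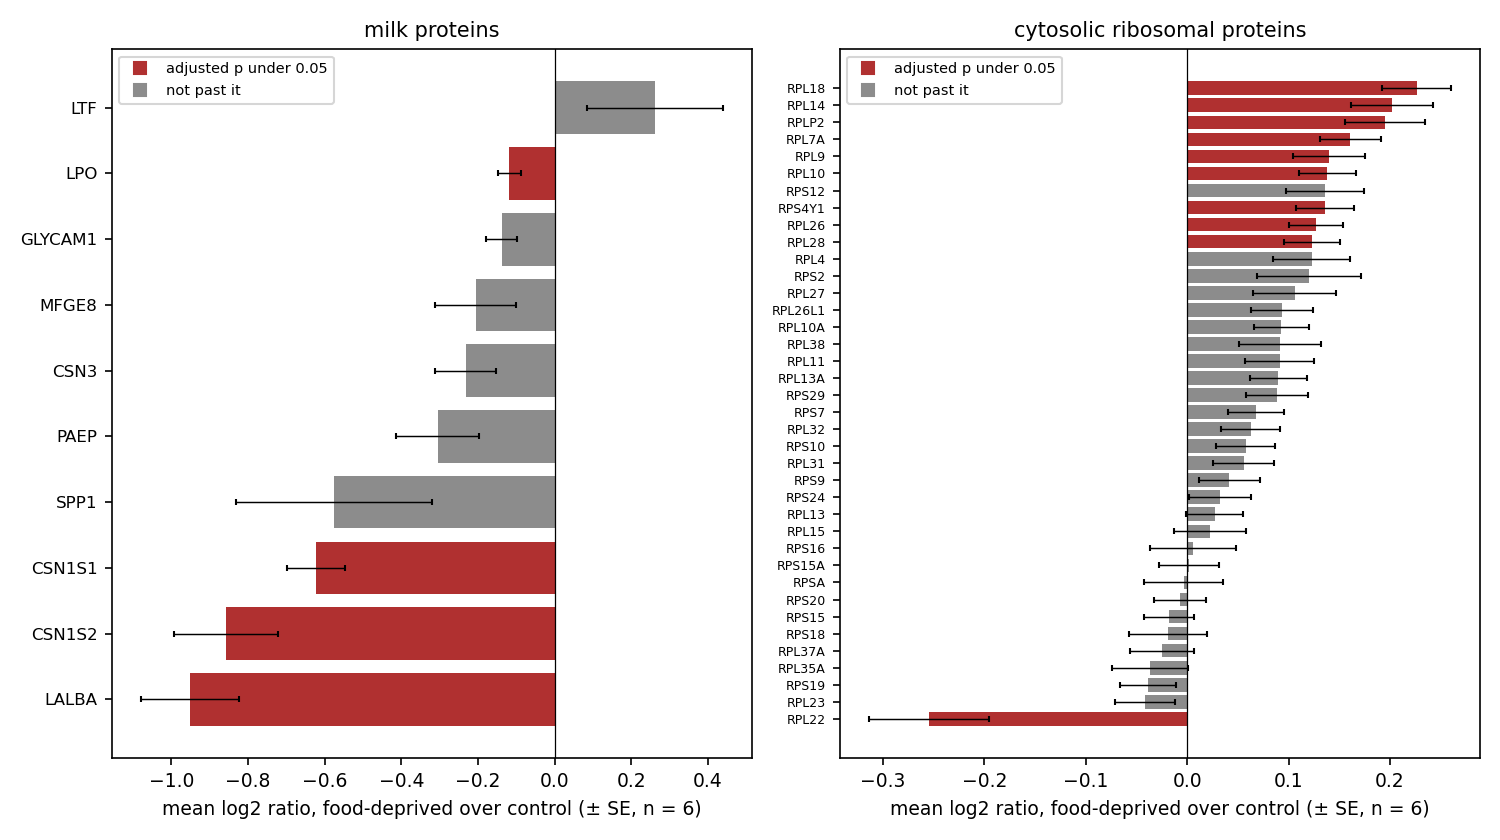
Mean log2 ratio of food-deprived over control (horizontal axis) for each measured milk protein gene and each cytosolic ribosomal protein gene, as bars with limma's moderated standard error over 6 comparisons, red where the adjusted p is under 0.05. Of the milk proteins 4 were lower, and of the ribosomal proteins 9 were higher and 1 was lower.

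Genes of fat synthesis moved singly and not as lists. FASN, the enzyme that builds medium-chain fatty acids, fell (-0.46 ± 0.38; adjusted p = 0.0310), but not without comparison 1, 3 or 4, where the adjusted p reached 0.105. INSIG1, a brake on sterol-regulated transcription, fell (-0.27 ± 0.17; adjusted p = 0.0127). PLIN2, the coat of cytoplasmic lipid droplets, rose (0.26 ± 0.15; adjusted p = 0.00663), and AGPAT3, an acyltransferase, rose (0.12 ± 0.052; adjusted p = 0.0219), losing its call without comparison 2, 3 or 4 (adjusted p up to 0.0704). MUC15, a mucin of the globule membrane, fell (-0.22 ± 0.12; adjusted p = 0.00840). FABP3, a fatty acid carrier, had -0.19 ± 0.16 (adjusted p = 0.0517) and MUC1, another membrane mucin, -0.14 ± 0.17 (adjusted p = 0.159). LPL, which frees fatty acids from plasma lipids, had -0.12 ± 0.10 (adjusted p = 0.0977). Its dye effect was 0.71 and the first array of each comparison alone gave 0.59. The means were -0.049 ± 0.058 for fatty acid synthesis and desaturation, -0.0016 ± 0.053 for fatty acid uptake and triglyceride synthesis, -0.063 ± 0.087 for the milk fat globule and -0.0070 ± 0.050 for cholesterol synthesis, with camera adjusted p of 0.879, 0.973, 0.453 and 0.973. Lactose synthesis and glucose supply had a mean of -0.075 ± 0.061 and a median of 0.030 (adjusted p = 0.955), and LALBA was its only called member of 10 measured.

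As a list, cytosolic ribosomal protein genes were higher by camera by a small amount, although 28 of the 38 did not pass singly. Their mean was 0.063 ± 0.015 (median 0.078, 29 of 38 genes above 0; camera adjusted p = 1.79e-05), above 0 in 6 of 6 comparisons (exact sign-flip p = 0.03125). With an estimated correlation the adjusted p was 0.0671. It was 0.070 in the first scan session and 0.057 in the second, and the adjusted p with session as a block was 1.55e-05. Over all probes 9 rose and 1 fell, and adjusted over the list alone 16 rose and 1 fell. The genes with the smallest p were RPL18 (0.23 ± 0.087; adjusted p = 0.00213), RPL14 (0.20 ± 0.12; adjusted p = 0.0127), RPLP2 (0.20 ± 0.11; adjusted p = 0.0125) and RPL7A (0.16 ± 0.068; adjusted p = 0.00837), all higher and all proteins of the large subunit. RPL22, also of the large subunit and named after its value was seen, fell (-0.25 ± 0.19; adjusted p = 0.0259), but not without comparison 1 or 3 (adjusted p up to 0.0918). Of the 12 largest rises over all genes, PABPC1, which binds the poly(A) tail, rose by 0.54 ± 0.26 (adjusted p = 0.00155), RACK1, a scaffold on the small subunit, by 0.27 ± 0.11 (adjusted p = 0.00199), and EIF3M, of an initiation factor, by 0.29 ± 0.20 (adjusted p = 0.0138). EIF3M lost its call without comparison 1 or 2 (adjusted p up to 0.0544). Translation factors as a list had a mean of 0.023 ± 0.012 (adjusted p = 0.637), with EEF1G (0.14 ± 0.068; adjusted p = 0.0173) and EIF4A3 (0.12 ± 0.062; adjusted p = 0.0339) higher and EIF6 (-0.19 ± 0.045; adjusted p = 0.00133) lower. EEF1G had -0.086 on the first array alone and EIF4A3 -0.060 on the second alone. EEF1G lost its call without comparison 2, 3 or 5 (adjusted p up to 0.0527), EIF4A3 without any of comparisons 1 to 5 (adjusted p up to 0.110), and a second probe of EIF4A3 gave 0.010.

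Other rises included HSPA8, a constitutive chaperone (0.40 ± 0.35; adjusted p = 0.0388), ZNF473, a zinc finger protein of histone RNA processing (0.40 ± 0.35; adjusted p = 0.0372), ACTG1, a cytoskeletal actin (0.30 ± 0.14; adjusted p = 0.00281), and ELF5, a transcription factor of secretory cells (0.26 ± 0.14; adjusted p = 0.00461). KRT19, a keratin of simple epithelium, had 0.23 ± 0.17 (adjusted p = 0.0268) and LOC784446, not described further in the annotation, 0.22 ± 0.15 (adjusted p = 0.0218). A second probe of KRT19 gave 0.0090. The calls of MT1A and HSPA8 were lost without comparison 2, 3 or 4 (adjusted p up to 0.102 and 0.112), that of ZNF473 without 2, 3 or 5 (up to 0.125), and those of KRT19 and LOC784446 without 1, 2 or 3 (up to 0.0918 and 0.0756). Of the 12 largest rises, 6 kept their call in every such fit. Under a trended, robust variance 7 probes in all were called higher, so the 12 cannot all have kept it there.

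**Figure D2:**
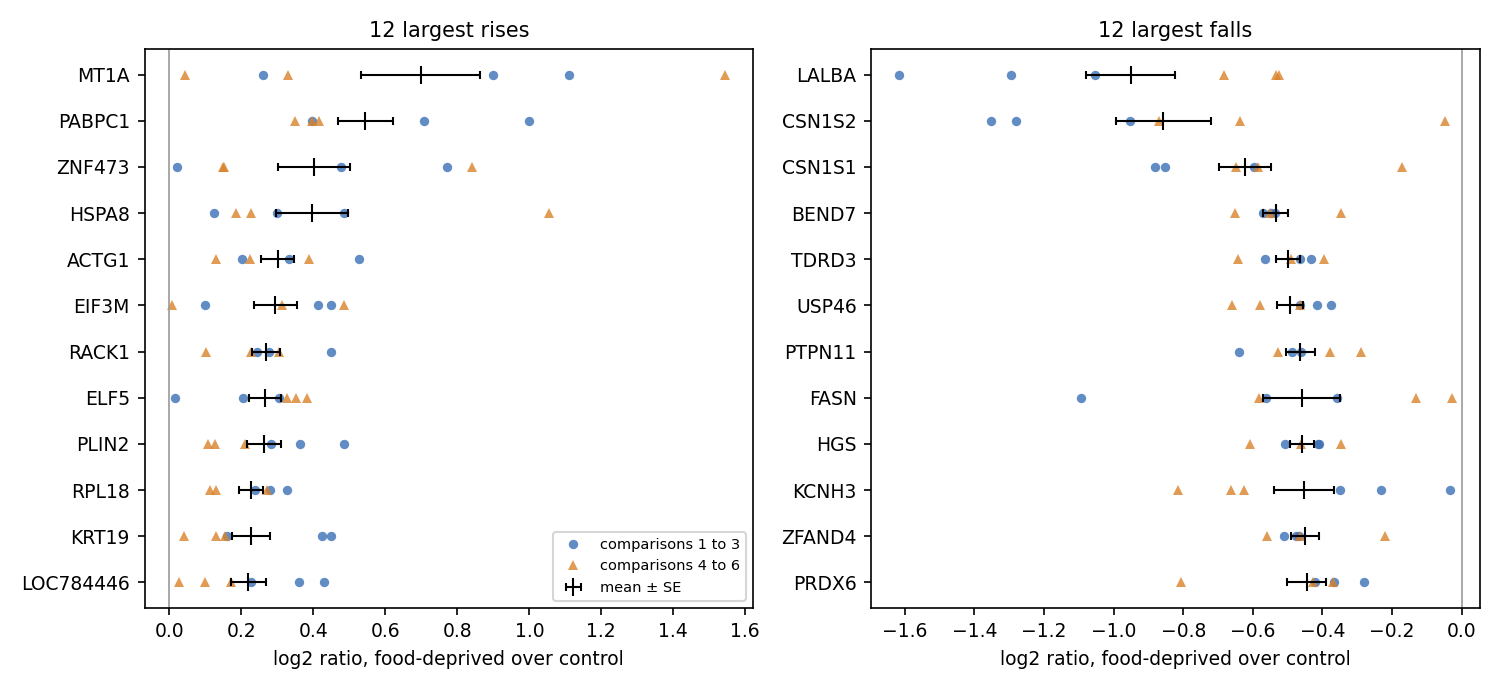
Log2 ratio of food-deprived over control (horizontal axis) in each of the 6 comparisons for the 12 largest rises and the 12 largest falls, with the mean and limma's moderated standard error; circles are comparisons 1 to 3 and triangles comparisons 4 to 6. MT1A ranges from 0.042 to 1.54, and LALBA lies lower in comparisons 1 to 3 (mean -1.32) than in comparisons 4 to 6 (mean -0.58).

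The remaining large falls were in genes of varied function. BEND7, with a DNA-binding BEN domain, fell by 0.53 ± 0.10, TDRD3, a reader of methylated arginine, by 0.50 ± 0.091, USP46, a deubiquitinase, by 0.49 ± 0.11, and PTPN11, a tyrosine phosphatase of growth factor signalling, by 0.46 ± 0.12 on the log2 scale. HGS, of endosomal sorting, fell by 0.46 ± 0.091, ZFAND4, a zinc finger protein, by 0.45 ± 0.12, PRDX6, a peroxiredoxin, by 0.45 ± 0.18, and KCNH3, a potassium channel, by 0.45 ± 0.30. KCNH3 had -0.20 in the first scan session and -0.70 in the second. The adjusted p of these 8 genes ran from 6.07e-05 for BEND7 to 0.00963 for KCNH3. Of the 12 largest falls, 11 kept their call without any single comparison, FASN being the exception. Each of these 8 genes has 1 tested probe. In 18 genes with several tested probes, 19 probes were called lower with a median of -0.18. The other probes of their genes, called or not, had a median of 0.011 (95% interval -0.050 to 0.022), 9 of the 19 values being of the same sign. Among genes chosen after their values were seen, SELENOF, a selenoprotein, had -0.43 and 0.027 in its probes, and TBX3, a transcription factor, -0.37 and 0.040. Over 10 genes called higher the medians were 0.20 and 0.022 (95% interval of the latter -0.0056 to 0.067). There 8 of the 10 values of the other probes were of the same sign. Called probes were picked for their size, so part of each gap follows from the choice. Of 28 genes with several tested probes and at least 1 called, 1 had all probes called.

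Among lists of energy metabolism, the means were -0.028 ± 0.026 for glycolysis, -0.029 ± 0.025 for the citrate cycle, -0.017 ± 0.011 for oxidative phosphorylation and 0.0073 ± 0.024 for fatty acid oxidation and fasting response, with camera adjusted p of 0.637, 0.531, 0.648 and 0.919. Single members fell, with PGAM1 of glycolysis at -0.28 ± 0.067, MDH2 of the citrate cycle at -0.29 ± 0.090, and NDUFB8 and ATP5MC3 of oxidative phosphorylation at -0.41 ± 0.11 and -0.26 ± 0.045. Their adjusted p were 2.81e-04, 5.27e-04, 1.63e-04 and 2.15e-04, and a second probe of PGAM1 gave -0.067. Of the 40 genes of oxidative phosphorylation, 20 lay above 0 and 20 below. ATP5MC2 lay above, at 0.21 (limma adjusted p = 0.0982 with session as a block). PPARA, a receptor of fasting metabolism, rose by 0.11 ± 0.052 (adjusted p = 0.0384), but not without any one of comparisons 1 to 5 (adjusted p up to 0.112).

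Among lists of protein handling, endoplasmic reticulum chaperones and unfolded protein response had a mean of 0.045 ± 0.022, protein entry into the endoplasmic reticulum 0.0031 ± 0.026, the proteasome 0.0062 ± 0.016 and heat shock proteins 0.032 ± 0.052 (camera adjusted p = 0.453, 0.919, 0.919 and 0.955). The amino acid deprivation response had 0.0026 ± 0.055, amino acid transporters 0.039 ± 0.038, autophagy 8.51e-04 ± 0.037 and the lysosome -0.012 ± 0.026 (0.955, 0.592, 0.919 and 0.919). HSPA8, described with the largest rises, was the called rise among heat shock proteins. Called falls included SRPRA, a receptor of secretion (-0.23 ± 0.12), STIP1, a co-chaperone (-0.20 ± 0.073), MAP1LC3A, of the autophagosome (-0.24 ± 0.055), and CTSK, a lysosomal protease (-0.19 ± 0.074), with adjusted p of 0.00659, 0.00245, 5.43e-04 and 0.00380. Of the proteasome PSME1 (-0.19 ± 0.10), PSMD1 (-0.23 ± 0.20), PSMB1 (-0.13 ± 0.071) and PSMB7 (-0.10 ± 0.049) fell, with adjusted p of 0.00916, 0.0442, 0.0246 and 0.0466. The PSMD1 probe was detected in 6 of 12 food-deprived and 8 of 12 control channels. Calls of the last 3 depended on single comparisons, with adjusted p up to 0.127 for PSMD1 without 1, 2, 3 or 4, up to 0.0850 for PSMB1 without 1, 3, 4 or 5, and up to 0.158 for PSMB7 without any of 1 to 5.

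Among lists of cell fate and regulation, the means were -0.0043 ± 0.011 for promoters and 0.030 ± 0.023 for opponents of programmed cell death, -0.027 ± 0.061 for mammary involution, -0.018 ± 0.010 for cell division, -0.025 ± 0.023 for hormone and growth factor signalling of lactation and 0.064 ± 0.074 for glucocorticoid and FOXO targets. The camera adjusted p were 0.973, 0.531, 0.531, 0.637, 0.453 and 0.955. The list of glucocorticoid and FOXO targets includes MT1A, the largest rise, which makes up most of its mean, and its median was 0.013. CIDEB, a lipid droplet protein also listed with cell death, fell (-0.22 ± 0.091; adjusted p = 0.00316), as did IGFBP5, a binder of insulin-like growth factor (-0.21 ± 0.073; adjusted p = 0.00187), ERBB3, a growth factor receptor (-0.28 ± 0.086; adjusted p = 6.60e-04), and NR3C1, the glucocorticoid receptor (-0.13 ± 0.078; adjusted p = 0.0293). SESN1, a stress-induced sestrin, rose (0.15 ± 0.11; adjusted p = 0.0429). NR3C1 was not past the threshold without 1, 2, 3 or 5 (adjusted p up to 0.0932), nor SESN1 without any of 1 to 5 (up to 0.126). CDC20, POLD1 and BUB1B of cell division fell, by 0.16 ± 0.033, 0.19 ± 0.047 and 0.23 ± 0.16 on the log2 scale (adjusted p = 0.00250, 0.00175 and 0.0225), BUB1B not without 2, 3, 4 or 5 (up to 0.0731). Antioxidant defence had -0.0050 ± 0.011, ion and mineral transport 0.021 ± 0.027 and interferon and antigen presentation 0.0079 ± 0.031 (camera adjusted p = 0.973, 0.637 and 0.826). PRDX3, a mitochondrial peroxiredoxin, had -0.11 ± 0.034 (adjusted p = 0.0282), lost without any of 1 to 5 (up to 0.0951), and 0.098 on the second array alone. IRF1, an interferon regulator, fell (-0.20 ± 0.086; adjusted p = 0.00464).

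Over all 6 comparisons camera called none of the sets of cell type markers, while in comparisons 4 to 6 alone it called adipocyte markers (adjusted p = 0.0367). Luminal epithelium had a mean of 0.065 ± 0.054, myoepithelium and smooth muscle -0.010 ± 0.062, fibroblast and connective tissue -0.022 ± 0.032, adipocyte -0.080 ± 0.024 and endothelium -0.0020 ± 0.018 (adjusted p = 0.453, 0.919, 0.826, 0.335 and 0.973). T cells had 0.0025 ± 0.029, B and plasma cells -0.013 ± 0.10, macrophages and neutrophils -0.033 ± 0.025 and skeletal muscle -0.048 ± 0.033 (adjusted p = 0.973, 0.919, 0.453 and 0.453). Erythrocyte markers had 2 measured genes and were not tested as a set. OCLN, a tight junction protein, rose (0.13 ± 0.076; adjusted p = 0.0310), and KRT8, a luminal keratin, had 0.22 ± 0.25 (adjusted p = 0.129). The adipocyte genes LEP, a hormone (-0.33 ± 0.20; adjusted p = 0.00838), and CIDEC, a lipid droplet protein (-0.19 ± 0.073; adjusted p = 0.00367), fell, and a second probe of LEP gave 0.037. FCGR2B, an immunoglobulin receptor (-0.23 ± 0.18; adjusted p = 0.0339), SPARC, a matrix protein (-0.18 ± 0.12; adjusted p = 0.0237), CKM, a muscle kinase (-0.20 ± 0.13; adjusted p = 0.0206), and ALAS2, of haem synthesis (-0.12 ± 0.043; adjusted p = 0.0204), were lower. These 5 calls, OCLN included, were lost without 3 or 4 of the comparisons each, with adjusted p up to 0.104 for OCLN (1, 2, 3 or 5), 0.109 for FCGR2B (1, 2, 4 or 6), 0.0713 for SPARC (2, 4 or 5), 0.0755 for CKM (1, 2 or 3) and 0.0731 for ALAS2 (1, 2 or 4). The SPARC probe was detected in 4 of 12 food-deprived and 7 of 12 control channels, so its value lies near the background. On the second array alone OCLN had -0.013, FCGR2B 0.067 and ALAS2 0.039.

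Of the 38 sets tested, camera called 2 with the preset and 0 with the estimated correlation, and fry called 5, adding endoplasmic reticulum chaperones upward (adjusted p = 0.0285), adipocyte markers downward (0.0285) and cell division downward (0.0446). The exact sign-flip p was at its smallest, 0.03125, for 11 of the 38 sets, the 2 called by camera among them, so it does not set these apart. The other 9 were lactose synthesis, oxidative phosphorylation, cell division and adipocyte markers, each below 0 in all 6 comparisons, and translation factors, endoplasmic reticulum chaperones, amino acid transporters, opponents of cell death and luminal epithelium, each above 0. For lactose synthesis this rests on LALBA, which the list shares with milk proteins, and 7 of its 10 genes lay above 0. Mean and median differed in sign for lactose synthesis, fatty acid uptake, cholesterol synthesis, oxidative phosphorylation, the amino acid deprivation response, promoters of cell death, cell division, the lysosome, antioxidant defence, endothelium and T cells. Camera's direction followed the median for lactose synthesis, cholesterol synthesis, the amino acid deprivation response, antioxidant defence and T cells, and the mean for the others. No set differed between scan sessions, the smallest adjusted p being 0.237.

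Over all 6676 probes tested, 455 passed an adjusted p of 0.05, 104 higher and 351 lower in food-deprived goats, 417 of them of one sign in all 6 comparisons. The variance model decided much of this, above all for the rises, with 7 higher and 264 lower under a trended, robust variance and 11 higher and 77 lower under unmoderated variances. At an unadjusted p of 0.05 there were 1356. With at least a 1.5-fold change there were 5, namely MT1A, LALBA, CSN1S2, CSN1S1 and probe 1001864571, which has no gene name, had -0.59 (adjusted p = 0.00183) and was chosen after its value was seen. The median was 0.14 for the probes called higher, -0.21 for those called lower and 0.0076 for all. With scan session as a block 455 passed, in comparisons 1 to 3 alone 252 and in comparisons 4 to 6 alone 95. Of the 455 probes, 214 also passed in comparisons 1 to 3 alone and 91 in comparisons 4 to 6 alone, and over all tested probes the session means had an r of 0.58. Comparison 6 shared least with the others (r across probes 0.16 to 0.30, against 0.34 to 0.46 among comparisons 1 to 5), and without it 569 passed, 203 higher. Without comparison 2, 300 passed, 35 of them higher.

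**Figure D3:**
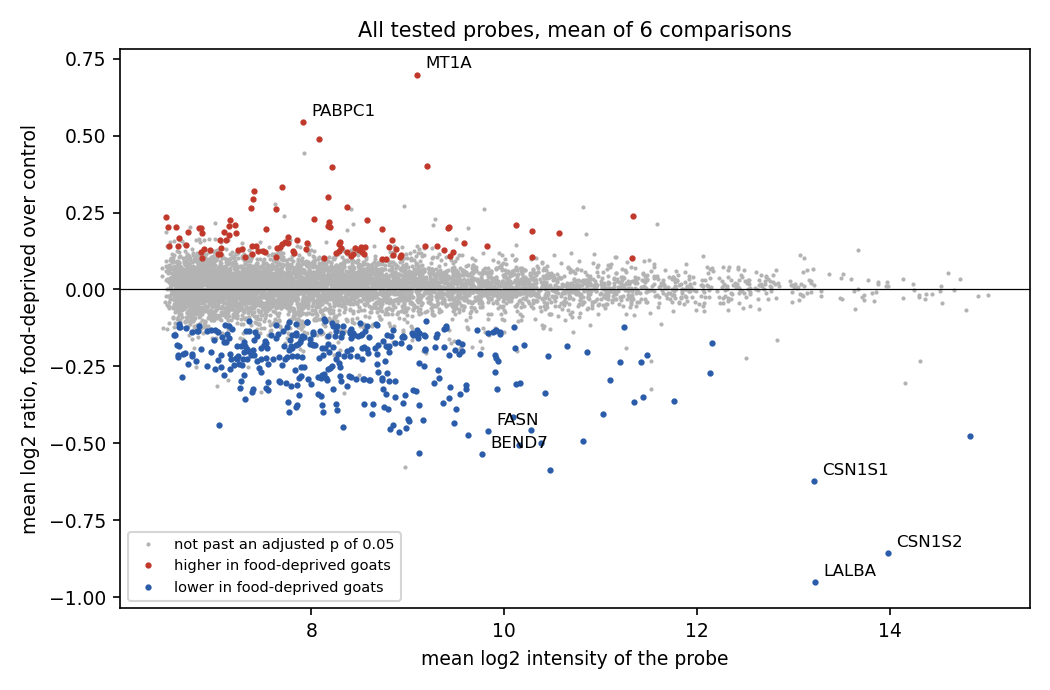
Mean log2 ratio of food-deprived over control (vertical axis) against mean log2 intensity (horizontal axis) for 6676 probes, 1 point each, with probes past the adjusted p in red (104 higher) and blue (351 lower). The median of the falls is -0.21, while LALBA, CSN1S2 and CSN1S1 lie at high intensity and lower.

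The dye moved more probes than the diet, with a median absolute effect of 0.090 against 0.035. It had an effect on 3424 probes (51.3%), 1743 brighter in Cy5 and 1681 in Cy3, and 218 of the 455 were past both tests. The dye-swapped arrays of one comparison, both as food-deprived over control, had r across probes of -0.39 to -0.23, while arrays of one orientation had 0.46 to 0.72. The counts rest on the pairing on the array. Taking the channels as 6 against 6 goats, limma called 0 probes, and 32 had an unadjusted p under 0.05. In log2 intensity the median SD over the 6 channel values was 0.295 for food-deprived and 0.299 for control, against 0.077 for the ratios. The channel values come from different arrays, so this SD mixes array and scan session differences with those between goats. A ratio still holds the difference between the goats of a pair, which pairing on the array does not remove.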

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

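Of the tests in this part, that of the sign patterns and that of mitochondrial ribosomal proteins were set before their results were seen; those of dye bias, other probes, genes of other tissues, the CSN1S1 signal and the terminal oligopyrimidine class were chosen only after. For genes of other tissues an added lower bound on the share, set once the share was known, decided the outcome.

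A single comparison lay far from the other 5 in 6 of 119 groups of 6 values, which is 5.04%, where the same rule marked 5.13% of groups simulated from 1 normal distribution. These were ZFAND4 at -0.22 in comparison 6 (others -0.56 to -0.46), PRDX6 at -0.81 in comparison 4 (others -0.43 to -0.28) and CIDEB at -0.39 in comparison 2 (others -0.22 to -0.14). AGPAT3 was at 0.23 in comparison 4 (others 0.085 to 0.12), PPARA at 0.0089 in comparison 6 (others 0.10 to 0.15), and the markers of B and plasma cells at 0.18 in comparison 4 (others -0.11 to -9.00e-04). That is as many as chance gives, and no pattern was read from them.

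Chance is unlikely to account for the number of probes past the threshold. Of the 32 sign patterns of the 6 comparisons 1, the real one with 455 probes, gave as many, and the highest of the others gave 5. Turning comparisons 4 to 6 alone gave 0. A share of 1 in 32 is the smallest this test can give. Turning signs also adds variance to any effect shared by the comparisons, which lowers the other counts. A shared technical effect would act in the same way.

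Most of the 351 probes called lower changed little, with a median of -0.21. A straight-line trend on the dye effect does not account for them, since 345 probes were still called lower once it had been removed. Averaging both dye orientations had already cancelled an additive dye effect, so little was left to remove. Whether another form of dye bias adds to these falls was not tested. A signal particular to single probes may explain part of them, since for 19 probes called lower the other probes of their 18 genes, called or not, had a median of 0.011 (95% interval -0.050 to 0.022) against -0.18, a gap to which picking called probes also adds. Genes of other tissues decided nothing, with 5.41% of 37 detected probes called lower (exact 95% interval 0.661 to 18.2%) against 5.36% of the others. A true fall of single transcripts or their variants stays open, since the other probes of a gene can lie on other transcripts.

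The CSN1S1 probe was dimmer in the second scan session, where its log2 intensity fell by 2.89 in food-deprived goats and fell by 3.19 in control goats, the largest fall of 6653 probes in both. The brightest 1% of probes could not test a general loss of brightness of strong probes. The intensities follow Aquantile normalization, which gives all arrays 1 distribution of mean intensity, so strong probes as a class could hardly differ. Their median rose by 0.22 in food-deprived and 0.15 in control goats. A loss shared by strong probes would have been removed there, so the fall of CSN1S1 is one relative to other probes. A print or slide batch acting on single probes could not be told apart from a difference between goats: MYOZ2, the next in line, fell by 2.17 in food-deprived and fell by 2.18 in control goats, and 93 other probes fell by at least 1 in both. Each session holds other goats, 3 per diet, and no p is given, since the probe was picked for the size of its fall. Goats can differ in casein alleles, which was not tested, as no genotype was used here.

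Whether other transcripts of the terminal oligopyrimidine class share the rise of cytosolic ribosomal protein genes stays open: their mean was 0.039 over 13 genes, above 0 in 6 of 6 comparisons (camera p = 0.0354, adjusted over 3 sets 0.0531, 0.0765 with an estimated correlation). That class was drawn up after the ribosomal rise was seen, left out PABPC1, RACK1, EIF3M and EEF1G, whose rises had been seen, and has 6 genes in the list of translation factors. TPT1, chosen after its value was seen, was its 1 called gene (0.14; adjusted p = 0.00659). Mitochondrial ribosomal protein genes did not share the rise, with a mean of -0.011 over 44 genes. A change shared by this class may be put as a hypothesis only, and no value here separates transcription from RNA stability.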

How the results depend on the processing

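Scan session as a block, each session alone and removal of the dye trend were chosen after seeing the data. Within 1.5 times the reported counts were 20 of 27 alternatives for the total (328 to 634), 15 for probes higher (85 to 152) and 21 for probes lower (264 to 455). Of the 455 probes, 420 were shared with the deposited ratios, 425 with no background correction and 419 with median centring. Aquantile normalization between arrays leaves ratios as they are, so it tested nothing though it is counted here.

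Single orientations hold the dye effect by construction: the first array of each comparison alone gave 2752 probes (1431 higher, 1321 lower) and the second alone 2621 (1288 higher, 1333 lower). Separate channels without a replicate block gave 0, 0 higher and 0 lower, with 32 at an unadjusted p under 0.05 in limma. By construction, variation shared by both channels of a spot no longer cancels there. Unmoderated variances gave 88 (11 higher, 77 lower), and a trended, robust variance 271 with 7 higher. Comparisons 1 to 3 alone gave 252 (56 higher, 196 lower) and comparisons 4 to 6 alone 95 (5 higher, 90 lower), with fewer samples each. Probes higher were 64 with background subtracted, 60 with the first spot only, 198 with 12 arrays and a replicate block, 184 with a dye term added and 179 with a common variance; the cause was not tested.

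Leaving out 1 comparison gave 300 to 569 probes, 35 to 203 higher and 265 to 366 lower. Probes higher were 55, 35, 49 and 62 without comparisons 1, 2, 3 and 5, and 203 without comparison 6. The dye effect ranged from 2987 to 3171 probes. Milk proteins and cytosolic ribosomal proteins were called in every such fit. Over the other settings camera called 2 lists, or 3 in comparisons 4 to 6 alone, where adipocyte markers were added, but 0 with an estimated correlation while fry, which does not compare a list with other genes, called 5.

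Among single genes, 11 pairs of gene and setting reversed, 427 lost a call, 51 gained one and 2072 kept their direction and side. On the first array alone EEF1G had -0.086 and LPL 0.59. On the second alone CSN3 had 0.093, GLYCAM1 0.039, LPO 0.032, FCGR2B 0.067, OCLN -0.013, EIF4A3 -0.060, ALAS2 0.039 and PRDX3 0.098. LTF had -0.16 in comparisons 4 to 6. For LTF the cause was not tested. Signal over background limits dim probes, and without a filter on them 407 probes were called.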
